A study of Caenorhabditis elegans with 9 samples.

How the data were processed

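PolyA RNA was measured by RNA-seq in germ lines dissected from young adult Caenorhabditis elegans, in 9 libraries. Per the labels, the animals were grown at 25 °C on OP50 bacteria, RNA was extracted with TRIzol, treated with Turbo DNase and made into Illumina TruSeq libraries, and all libraries carry batch label 1. The 4 groups were taken from the sample titles. P0_wt has 3 libraries of control animals of strain FAS158 that had lost a transgene array encoding the histone mutant H3.3K27M, P0_array has 2 libraries of subfertile animals that carried the array and were kept on tetracycline, and F3_fertile and F3_subfertile have 2 libraries each, from descendants of subfertile animals kept without tetracycline. The label that names the control libraries calls them N2, the usual wild-type strain, while the source label calls them FAS158 without the array, so the strain of P0_wt is not certain. Both F3 groups are individuals of one subfertile line of descent per the series' design text, judged fertile or subfertile by their eggs laid before dissection. The labels do not say whether the F3 animals carried the array. The labels do not say whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

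Per the submitters' processing notes, the tools were bcl2fastq, Salmon 1.10.3 and DESeq2, and the genome build was WBcel235. The authors deposited one table of estimated counts (expected counts) per gene and library, not normalized and with replicates not pooled. Between 96.6% and 97.7% of the values of a library were whole within 0.001. The annotation release, the handling of strand and any filter used by the authors are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may have been divided in ways that cannot be checked. This applies to the histone, major sperm protein, vitellogenin and collagen families, whose single members are therefore uncertain.

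Estimated counts were rounded to whole numbers. The table held 47339 gene identifiers, of which 46612 matched the Ensembl release 115 annotation of WBcel235, which gave positions, and 44022 had a symbol in the names table. Total counts ran from 38696403 to 47430300 per library, and 30220 genes had no count. Levels are CPM (counts scaled to library size) with TMM-scaled library sizes, given as mean ± SD over the libraries of a group. Where a group had 0 counts in every library, a fold change is a lower bound computed against 3 counts over the whole group, and no fold is given where both groups had at most 3 counts. These floors cover counting error only, since reads without molecular identifiers are not independent molecules.

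The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), fitted to all 9 libraries with 4 group means and 5 residual degrees of freedom, on the 13590 genes that passed filterByExpr. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The comparisons were P0_array, F3_subfertile and F3_fertile against P0_wt, F3_subfertile against F3_fertile and against P0_array, and the interaction, that is the difference between the P0_array minus P0_wt effect and the F3_subfertile minus F3_fertile effect. The 26 gene lists and the X chromosome were tested with limma's camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation. The lists were spermatogenesis and sperm, major sperm proteins, oogenesis and eggshell, germline proliferation and RNA regulators, P granules and small RNA pathways, meiotic chromosomes, PRC2 and other chromatin regulators, histone H3.3 genes, other histone genes, JNK pathway, DNA replication, apoptosis and DNA damage, mitochondrial stress response, mitochondrial genome protein genes, mitochondrial ribosomal proteins, cytosolic ribosomal proteins, heat shock with oxidative stress and detoxification, innate immunity and pathogen response, intestine markers, muscle markers, hypodermis and cuticle markers, collagen family, neuronal markers, somatic gonad and basement membrane markers, developmental transcription factors, and sex determination and dosage compensation. Camera p-values of lists were adjusted over the 26 lists within a comparison.

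The genes named were chosen by a rule. In each comparison these were, among genes past the threshold with no overlap between the libraries of the groups compared and a mean of at least 5 CPM in one of them, the 10 with the largest rise and the 10 with the largest fall. Up to 4 members of each list with the smallest p were added, together with the H3.3 genes and mes-2, mes-3 and mes-6 in every comparison. For the interaction the rule took up to 5 genes in each direction. Genes named outside the rule are marked where they appear. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

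The alternatives were DESeq2 1.42.0, limma-trend, RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in every library of a group with a mean count of 50, a fit to only the groups compared, the replicate number as a block, a test against a 1.5-fold change, and each library left out in turn. Gene lists were also tested with fry. Alternatives chosen after the data were seen restricted the genes to those with a mean of at least 20 CPM over P0_wt and F3_fertile, and applied the estimated correlation, the block and left-out libraries to the X chromosome and to the overlaps. Silent genes were defined as genes under 1 CPM in every P0_wt library. Their number was 38526.

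The test was checked on simulated counts drawn for P0_array against P0_wt, with 12808 genes tested. Of 100 genes changed 2-fold it called 14 and of 100 changed 4-fold it called 69, all in the right direction, with 2 false calls. On the same simulated data, DESeq2 called 138 of the 200 changed genes with 113 false calls, and limma called 99 with 6 false calls. Comparisons that share the control libraries were set beside 30 simulations in which no group was changed.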

Results

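Germ lines of young adult C. elegans were profiled by polyA RNA-seq in 9 libraries of 4 groups. P0_wt (n = 3) held control animals without the H3.3K27M array, a transgene for a histone H3.3 that carries methionine in place of lysine 27. The source label calls the controls strain FAS158 that lost the array, while the library names call them N2. P0_array (n = 2) held subfertile animals with the array on tetracycline. F3_fertile (n = 2) and F3_subfertile (n = 2) held fertile and subfertile individuals from descendants of subfertile animals, raised without tetracycline. The labels do not say whether they carried the array. Total counts were 40998545, 47430300 and 45555584 in P0_wt, 44240748 and 43248404 in P0_array, 41939820 and 40606745 in F3_fertile, and 38696403 and 43615842 in F3_subfertile. Between 10415 and 10839 genes had counts in each library of the fertile groups, against 12558 to 14590 in each library of the subfertile groups. The first principal component held 54.4% of the variance and placed the subfertile libraries between 130.8 and 175.6 and the fertile libraries between -144 and -81.2.

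The comparison of P0_array with P0_wt asked how germ lines of subfertile animals with the array differ from controls. Array and subfertility change together in it, and the labels do not say whether the controls were kept on tetracycline. Genes known from intestine, cuticle, muscle and pathogen defence were higher in P0_array. Over all genes, 763 of 996 rises started from under 1 CPM in P0_wt. Muscle markers, in contrast, already took 0.0884% to 0.117% of counts in P0_wt, and 0.313% and 0.328% in P0_array. H34I24.2 (III: 2842044 to 2845197, WBcel235) had no counts in P0_wt and 803.1 ± 200.3 CPM (SD, n = 2) in P0_array, at least 36500-fold higher (edgeR adjusted p = 0.000734). The collagen col-179 was at 502.5 ± 45.12 CPM (at least 23300-fold), the C-type lectin clec-150 at 365.3 ± 129.5 CPM (at least 16500-fold), the lysozyme lys-10 at 363.8 ± 212.3 CPM (at least 16200-fold) and lgmn-1 at 323.2 ± 92.14 CPM (at least 14700-fold), each with 0 counts in P0_wt. The remaining genes of the 10 largest rises were irg-8, which went from 0.00759 to 1442 ± 345.7 CPM, and B0024.4, C14C6.5, ilys-2 and F54E2.1, all from 0 counts. The ilys-2 call was lost when any 1 of the P0_wt libraries was left out.

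Of 20 tested intestine markers 15 rose in P0_array and none fell (20 adjusted over the list alone). They included the protease cpr-1 (169.9 ± 9.36 CPM against 0 counts, at least 7800-fold), the peptide transporter pept-1 (log2 fold change 10.68 ± 1.24 SE) and the desaturase fat-6 (10.38 ± 0.96). The 6 vitellogenin genes, which encode yolk proteins made in the intestine, took 9.14% and 2.32% of the counts of the P0_array libraries and at most 0.054% in P0_wt. Of the 86 collagens of the list, which leaves out dpy-17 (below), 28 rose and none fell (33 up and 1 down adjusted over the list alone), among them col-119 (1200 ± 107 CPM against 0.909 ± 0.635), col-80 (986.1 ± 34.56 against 3.76 ± 1.90) and col-140 (2239 ± 48.9 against 3.86 ± 3.51). Of 9 hypodermis and cuticle markers 3 rose (5 adjusted over the list alone). Muscle markers gave 9 rises in 22 (12 adjusted over the list alone), with tropomyosin lev-11 up by 2.00 ± 0.15, paramyosin unc-15 by 2.18 ± 0.23 and actin act-4 by 1.36 ± 0.14 on the log2 scale. In the innate immunity list 8 of 13 rose (11 adjusted over the list alone), led by the lysozymes lys-2 (233.1 ± 17.9 CPM) and lys-1 and by irg-4. Camera placed each of these lists higher, with adjusted p = 6.27e-09 for intestine, 2.38e-05 for collagens, 0.0096 for hypodermis, 0.00119 for muscle and 3.59e-06 for immunity. With an estimated correlation the calls were lost, at adjusted p = 0.18 for intestine, collagens, muscle and immunity and adjusted p = 0.299 for hypodermis, whose call was also lost without P0_array replicate 2. For muscle the estimated correlation was -0.021, below the preset 0.01, so that loss does not reflect correlation between its genes. Silent genes took 2.68% and 4.08% of counts in the P0_array libraries, against 0.06% to 0.07% in P0_wt, where they are low by definition. In F3_fertile, whose libraries did not define them, they took 0.18% and 0.16%.

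**Figure D1:**
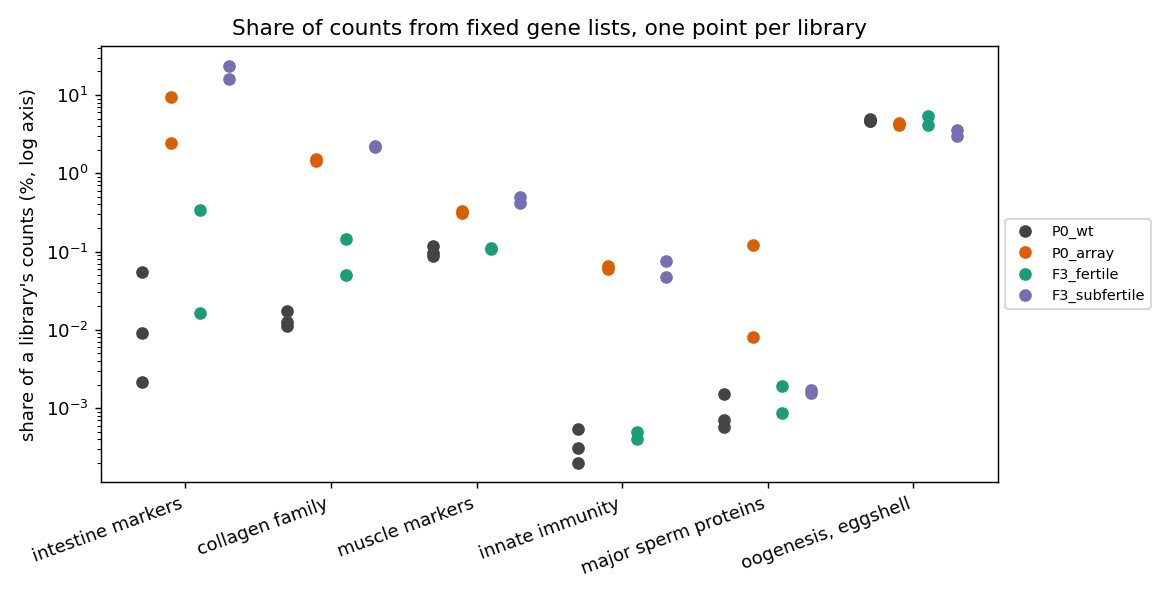
Share of each library's counts (percent, log axis) taken by 6 gene lists, with 1 point per library and colours for the 4 groups. Intestine markers took 2.45% to 23.6% in the subfertile libraries and at most 0.338% in the fertile ones, and oogenesis and eggshell genes took 2.95% and 3.61% in F3_subfertile and 4.14% to 5.37% in the other 7 libraries. These are parts of a whole: vitellogenin genes alone took 23.02% and 15.4% in F3_subfertile, which lowers every other share there. Of 27 oogenesis genes 0 were called in F3_subfertile against F3_fertile.

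Major sperm proteins took a larger share of counts in both P0_array libraries than in P0_wt, to very different degrees, while other sperm genes did so in replicate 3 alone (0.0693%, against 0.0277% in replicate 2 and 0.0328% to 0.0356% in P0_wt). The major sperm proteins, the cytoskeletal proteins of nematode sperm, took 0.122% of the counts of P0_array replicate 3 and 0.00809% of those of replicate 2, against 0.00151% or less in P0_wt. Of 27 tested, 11 rose (25 adjusted over the list alone), such as msp-38 (61.68 ± 80.4 CPM against 0.390 ± 0.213), with camera adjusted p = 6.13e-07 and adjusted p = 0.343 with an estimated correlation. Of 30 other sperm genes 1, ssp-9, rose (1 adjusted over the list alone; camera adjusted p = 0.132). Neuronal markers gave 4 rises in 19 (4 adjusted over the list alone; camera adjusted p = 0.216): sbt-1, egl-3, nlp-21 and flp-9. Of 20 stress and detoxification genes 4 rose and 1 fell (6 and 4 adjusted over the list alone), including the catalases ctl-1 and ctl-2 and the glutathione transferase gst-4, with camera adjusted p = 0.959. Without P0_array replicate 3 the calls of ssp-9 and msp-38 were lost. Without P0_wt replicate 2 or 3 those of ssp-9, msp-38, sbt-1 and nlp-21 were lost, and without any 1 library of P0_wt or P0_array that of flp-9. The gst-4 call was lost without P0_wt replicate 3, and that of rps-22 below without P0_wt replicate 1 or 2, either P0_array library or F3_subfertile replicate 3. Among 78 cytosolic ribosomal protein genes rpl-25.1 rose from 3.05 ± 1.22 to 161.7 ± 34.64 CPM and rps-22 fell (1 up adjusted over the list alone). Camera placed them (adjusted p = 6.13e-07) and 70 mitochondrial ribosomal protein genes without a call (0 adjusted over the list alone; adjusted p = 0.000278) lower, with adjusted p = 0.598 and adjusted p = 0.33 with an estimated correlation. No call was made among the JNK pathway (2 adjusted over the list alone; camera adjusted p = 0.512), mitochondrial stress (0; 0.978), mitochondrial genome (0; 0.512), gonad and basement membrane (0; 0.487) and developmental transcription factor lists (0; 0.935).

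Lists of germline function shifted lower by small amounts in P0_array, and few of their members passed the test. Their medians ran from -0.15 to -0.33 on the log2 scale. Autosomal genes of 20 CPM or more in the fertile groups were lower too (median -0.11), as were those of 100 CPM or more (-0.25). Camera compares a list with all tested genes, whose autosomal median was 0.23. Its calls thus do not set these lists apart from other expressed genes. The cytosolic and mitochondrial ribosomal lists above had medians of -0.21 and -0.1. The poly(A) polymerase gld-2 fell from 967.7 ± 108 to 512.2 ± 76.9 CPM (log2 -0.92 ± 0.19). The P granule genes car-1, ppw-2 and meg-4 fell by 0.52, 0.81 and 0.86 on the log2 scale, and him-17 and dsb-1, which act in meiotic recombination, fell by 0.74 and 0.68. zyg-12 (meiosis), jmjd-1.2 (chromatin), the replication genes orc-1, orc-5 and mcm-3, and clk-2 (DNA damage) also fell. Called falls were 1 of 13 proliferation and RNA regulators (2 adjusted over the list alone), 3 of 35 P granule and small RNA genes (12, with 1 rise), 3 of 29 meiotic genes (7), 1 of 21 chromatin regulators (2), 3 of 35 replication genes (3) and 1 of 16 apoptosis and DNA damage genes (1), with 0 of 27 oogenesis and 0 of 18 sex determination genes (0 and 0). Camera placed all 8 lists lower, with adjusted p from 3.40e-06 (P granules) to 0.00201 (chromatin regulators) and adjusted p = 0.18 or above with an estimated correlation. All 12 calls named here were lost without P0_array replicate 3, and each also without 1 or more of P0_array replicate 2 and P0_wt replicates 1, 2 and 3. The tissue markers above moved in the same libraries, and the share of counts from oogenesis genes was 4.38% and 4.17% in P0_array against 4.68% to 4.88% in P0_wt.

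Among the H3.3 genes, the gene class that the array's mutant protein belongs to, his-72 rose from 47.17 ± 8.13 to 98.93 ± 32.1 CPM (log2 1.07 ± 0.26, adjusted p = 0.0401), a call lost in 9 alternative settings, among them without any 1 of the P0_wt libraries, P0_array replicate 3 or either F3_subfertile library. Whether reads of the array are counted in it is not known. his-74 was at 53.03 ± 13.1 and 54.36 ± 8.18 CPM and his-71 at 0.26 and 1.34 CPM, while his-70 had 0 counts in P0_wt and 2.85 ± 4.03 CPM in P0_array. None of the 3 was called. The H3K27 methyltransferase genes were not called either: mes-2 was at 51.5 ± 16.6 and 41.1 ± 5.31 CPM, mes-3 at 10.8 ± 2.25 and 10.01 ± 3.81 CPM, and mes-6 at 778.3 ± 141 and 511.9 ± 90.2 CPM (adjusted p = 0.0774). The H3.3 list had 1 rise in 5 (1 adjusted over the list alone; camera adjusted p = 0.215), and 2 of 53 other histone genes, his-61 and his-68, fell, calls lost without P0_wt replicate 2 or 3 or either P0_array library (2 adjusted over the list alone; camera adjusted p = 0.512, directed lower, with a median of 0.22).

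The largest falls in P0_array were C55C3.3 (IV: 5685287 to 5688273), from 36.51 ± 1.15 to 1.31 ± 0.25 CPM (log2 -4.79 ± 0.29, adjusted p = 0.000734), Y23H5A.2, H14A12.5, WBGene00021651, sol-2, Y73F8A.26 (92.35 ± 11.18 to 11.81 ± 3.17 CPM), the cuticle collagen dpy-17, iglr-3, gadr-2 and lido-10. The call of Y23H5A.2 was lost without P0_array replicate 3, that of H14A12.5 without any 1 P0_wt library or P0_array replicate 2, and those of WBGene00021651, sol-2, gadr-2 and lido-10 without any 1 library of either group. Over all genes, edgeR called 996 higher and 218 lower of 13590 (1020 and 611 with upper-quartile scaling, which lowers every log2 fold change by about 0.22). Among genes of 20 CPM or more in the fertile groups 68 were higher and 89 lower. That limit uses the P0_wt mean itself and so takes out mostly rises. In P0_wt, 73 of the 996 rises and 198 of the 218 falls had 20 CPM or more. Of the 996 rises, 763 had under 1 CPM in P0_wt and 500 had no counts there. Without P0_wt replicates 1, 2 or 3 or P0_array replicates 2 or 3 the calls were 695, 625, 573, 784 and 678.

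The comparison of F3_subfertile with F3_fertile asked what goes with low fertility among descendants grown without tetracycline, and shares no library with the comparison above. Genes of the same tissues were higher in F3_subfertile. The 10 largest rises all started from 0 counts in F3_fertile: F54E2.1 reached 299.6 ± 155.7 CPM (at least 8510-fold, edgeR adjusted p = 0.00318), irg-4, named for its response to infection, 244.2 ± 19.5 CPM (at least 7210-fold), and cpr-1 151.3 ± 148.0 CPM (at least 4120-fold). They were followed in F3_subfertile by T16G1.7, F32H5.1, C34H4.2, T05E12.3, C05D12.3, Y105C5B.15 and C17H12.8 at 70.2 to 93.4 CPM. The calls of F32H5.1 and Y105C5B.15 were lost without F3_subfertile replicate 1, and that of F32H5.1 also without F3_fertile replicate 3. Of the 6 falls 4 met the naming rule: C06A6.2 (47.75 ± 31.8 to 6.06 ± 0.18 CPM), the glutathione peroxidase gpx-4, enee-1 and elpc-3. C06A6.2, enee-1 and elpc-3 were lost without F3_subfertile replicate 1, and C06A6.2, gpx-4 and elpc-3 without F3_subfertile replicate 3 or F3_fertile replicate 3.

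Muscle markers rose in 9 of 22 cases (12 adjusted over the list alone), with act-4 going from 696.6 ± 27.4 to 3030 ± 102.5 CPM (log2 2.12 ± 0.17), lev-11 up by 2.19 ± 0.17, unc-15 by 3.08 ± 0.28 and unc-89 by 4.64 ± 0.46. Intestine markers rose in 7 of 20 cases (18 adjusted over the list alone), such as fat-6, pept-1 and the acid phosphatase pho-1 (22.14 ± 10.4 CPM against 0 counts). Vitellogenin genes took 23.02% and 15.4% of counts in F3_subfertile and 0.33% and 0.016% in F3_fertile. Of 86 collagens 17 rose (27 adjusted over the list alone), such as col-122 (419.6 ± 80.4 CPM against 7.95 ± 5.31), of 13 immunity genes 6 rose (8) and of 9 hypodermis markers 2 rose (4). Camera gave adjusted p = 1.01e-06 for muscle, 1.01e-09 for intestine, 2.58e-05 for collagens, 1.16e-05 for immunity and 0.00244 for hypodermis. With an estimated correlation this was adjusted p = 0.0513 for muscle and adjusted p = 0.4 for the other 4. Silent genes took 3.15% and 2.19% of counts in F3_subfertile against 0.18% and 0.16% in F3_fertile.

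Basement membrane genes are shared by the somatic gonad and other tissues, and 2 of 22 rose (3 adjusted over the list alone; camera adjusted p = 0.0902): ost-1, from 65.1 ± 9.08 to 193.5 ± 14.3 CPM (log2 1.57 ± 0.20), and the type IV collagen let-2, whose call was lost without P0_wt replicate 1 or 3, F3_fertile replicate 3 or either F3_subfertile library. Against P0_wt, where ost-1 stood at 100.7 ± 17.8 CPM, the rise of ost-1 was 0.94 ± 0.17. The ribosomal protein genes rpl-25.1 and rpl-11.2 rose by 2.96 ± 0.38 and 1.93 ± 0.36, as 2 of 78 cytosolic ribosomal protein genes (2 adjusted over the list alone), while camera placed that list lower (adjusted p = 6.31e-05, and adjusted p = 0.771 with an estimated correlation). The detoxification genes ctl-2, gst-4 and gst-10 rose, as 3 of 20 (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.974). The histone gene his-15 rose by 2.49 ± 0.45 from 0.88 to 4.93 CPM, as 1 of 53 (4 adjusted over the list alone; camera adjusted p = 0.762). No member of the oogenesis, proliferation, P granule, meiotic, chromatin, replication, apoptosis, sex determination, H3.3, JNK, neuronal, sperm, major sperm protein, developmental transcription factor or mitochondrial lists was called (0 adjusted over the list alone, but 1 of 14 developmental transcription factors). Camera placed oogenesis (adjusted p = 0.00422), P granules (0.00436), meiosis (0.00219), replication (0.00874) and mitochondrial ribosomal proteins (0.00219) lower, with medians of -0.07 to -0.13 (mean 0 for replication) and adjusted p = 0.401 or above with an estimated correlation. Autosomal genes of 20 CPM or more in the fertile groups had a median of -0.12. These lists, and cytosolic ribosomal proteins at -0.15, thus stood near other expressed genes. Without F3_fertile replicate 1 the list calls of P granules and both ribosomal lists were lost, and without F3_fertile replicate 3 that of oogenesis. Lost without F3_subfertile replicate 1 were those of oogenesis and replication and the gene calls of his-15, rpl-11.2, gst-4 and gst-10. mes-2, mes-3, mes-6, his-72 and his-74 were not called, with adjusted p of 0.753, 0.145, 0.868, 0.865 and 0.945. In all, 508 genes rose and 6 fell (447 and 31 with upper-quartile scaling, 1437 and 83 by DESeq2), 275 of the rises from under 1 CPM in F3_fertile, and 167 genes were called without F3_subfertile replicate 1.

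The comparison of F3_subfertile with P0_wt asked what differed from controls in subfertile descendants. It gave 1132 higher and 112 lower genes (1116 and 466 with upper-quartile scaling), 800 of the rises from under 1 CPM in P0_wt. H34I24.2 (700.2 ± 258.7 CPM), col-179 (631.1 ± 165.7), the adult cuticle collagen col-19 (408.9 ± 5.51), the glyoxylate cycle enzyme icl-1 (348.6 ± 195.8), F54E2.1, the cytochrome P450 cyp-35C1 (285.4 ± 19.3), clec-150, lgmn-1, clec-218 and R193.2 all had 0 counts in P0_wt and were at least 8500-fold higher. Intestine (16 of 20; 19 adjusted over the list alone), muscle (11 of 22; 16), collagens (31 of 86; 35), immunity (7 of 13; 10), hypodermis (3 of 9; 4) and neuronal markers (4 of 19; 4) were called higher, and camera placed all 6 lists higher (adjusted p from 1.60e-10 for intestine to 0.0261 for neurons). Only muscle kept its call with an estimated correlation (adjusted p = 0.0481, and adjusted p = 0.236 for the others). The neuronal call was lost without P0_wt replicate 1 or any 1 library of P0_array or F3_subfertile. The lists of oogenesis, proliferation, P granules, meiosis, chromatin, replication, apoptosis, sex determination and mitochondrial ribosomal proteins were placed lower (adjusted p from 3.30e-05 for P granules to 0.0201 for mitochondrial ribosomal proteins, lost without P0_wt replicate 1), and at adjusted p = 0.236 to 0.538 with an estimated correlation. Their medians ran from -0.04 to -0.22, where autosomal genes of 20 CPM or more in the fertile groups had -0.12. Of 14 developmental transcription factors tbx-2 and pha-4 rose (2 adjusted over the list alone; camera adjusted p = 0.989), and of 22 gonad and basement membrane genes ost-1 and sth-1 (2; 0.947), all 4 lost without F3_subfertile replicate 1 or 3 or P0_wt replicate 2.

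The largest falls in F3_subfertile against P0_wt were R03D7.2 (20.41 ± 4.65 CPM to 0 counts, at least 458-fold lower), dyf-3, Y57G11C.1130, ZC317.7 (591.1 ± 87.9 to 42.01 ± 26.8 CPM, log2 -3.81 ± 0.41), his-9, cls-3, Y73F8A.26, H14A12.5, Y23H5A.2 and C55C3.3. R03D7.2, dyf-3, Y57G11C.1130, H14A12.5 and Y23H5A.2 lost their call without F3_subfertile replicate 1, and all of them but Y57G11C.1130 also without replicate 3 or P0_wt replicate 1. Of 53 histone genes 2 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.0841). him-17 (log2 -0.77 ± 0.14) and jmjd-1.2 (-0.62 ± 0.13) fell, as in P0_array, calls lost without F3_subfertile replicate 1, and rpl-25.1 rose by 3.2 ± 0.33. Without P0_wt replicate 2 or 3 or F3_subfertile replicate 1 or 3, 731, 740, 566 and 803 genes were called.

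P0_array and F3_subfertile shared 851 higher and 37 lower genes against P0_wt, with 0 in opposite directions, where independent lists of these sizes share 83.0 and 1.8. Across genes, which are not independent replicates, their log2 fold changes had Pearson r = 0.775, Spearman rho = 0.663 and a covariance of 10.6. With no group changed, the shared controls alone gave a mean of 0.03 shared calls, r = 0.401 and a covariance of 1.37 in 30 simulations. P0_array against P0_wt had a mean of only 0.2 calls there, so the 0.03 cannot show how many calls the controls make shared. The 3 controls cannot be split into sets of at least 2, so part of the excess may come from them. Without P0_wt replicates 1, 2 or 3 or F3_subfertile replicate 1 they shared 591, 498, 495 and 490 calls. Between P0_array against P0_wt and F3_subfertile against F3_fertile, which share no library, 418 genes were higher and 1 lower in both and 1 was opposite, where independent lists share 37.2 and 0.1, with r = 0.564, rho = 0.463 and a covariance of 7.17 (simulated r = 0.003). All comparisons came from 1 fit with a shared estimate of the spread, so the numbers for independent lists are only a rough guide. Fits of only the groups compared kept 1042 of 1214 calls in the P0 comparison and 286 of 514 in the F3 one. Most shared calls were of genes low in the fertile groups: among genes of 20 CPM or more there, the comparisons shared 35 calls, with r = 0.682 and rho = 0.091. Without F3_subfertile replicate 1 these shared 148 calls. F3_subfertile and P0_array differed directly at 1 gene, dhs-25, which was at 238 CPM in F3_subfertile and 28.5 in P0_array (log2 3.06 ± 0.18, edgeR adjusted p = 0.00177), a call lost in a fit of only these groups and with the replicate block. At an unadjusted p under 0.05 there were 1263 genes, and DESeq2 and limma called 351 and 261. Camera placed the major sperm proteins (median log2 -4.47, adjusted p = 2.34e-11) and other sperm genes (6.29e-05) lower and muscle (2.00e-05) and cytosolic ribosomal proteins (6.29e-05) higher in F3_subfertile than in P0_array. With an estimated correlation the adjusted p was 0.0838 for muscle and 0.952 for the other 3, and the call of the other sperm genes was lost without P0_array replicate 3 (adjusted p = 0.0914). The difference between the P0 and the F3 effect passed the test at 3 genes, dhs-25, C55C3.3 and the acyl-CoA synthetase gene acs-1, all lower in the P0 effect. Camera placed the interaction of sperm genes (adjusted p = 0.0354) and major sperm proteins (1.61e-08) higher and that of gonad and basement membrane markers (0.0488) lower, each at adjusted p = 0.946 with an estimated correlation. Without P0_array replicate 3, P0_wt replicate 1 or F3_subfertile replicate 1 the interaction calls of sperm genes and gonad markers were lost.

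The comparison of F3_fertile with P0_wt asked what remained different in descendants of normal fertility. It gave 27 higher and 15 lower genes (1205 at an unadjusted p under 0.05, 418 by DESeq2 and 78 by limma), of which 2 were kept with the replicate number as a block. Part of the rises were cuticle and other tissue genes also high in the subfertile groups: col-179 (17.1 ± 16.08 CPM against 0 counts), col-20 (49.1 ± 51.2 against 0.37 ± 0.32), col-119, col-80, icl-1 and the troponin tnt-2. Of 86 collagens 4 rose (23 adjusted over the list alone; camera adjusted p = 7.03e-06, and adjusted p = 0.534 with an estimated correlation), while F3_fertile replicate 1 had 0.144% and replicate 3 0.0504% of counts in collagens against at most 0.0176% in P0_wt. The other rises among the 10 largest were WBGene00043987, annotated on X (8.22 ± 0.13 CPM against 0 counts), bath-45, svop-1, C09G5.7 (42.3 ± 8.17 against 3.38 ± 1.92) and bath-13.

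The largest falls in F3_fertile were the adjacent histone genes his-9, his-14 and his-15 on chromosome II (13824849 to 13827098), from 27.2 ± 2.12, 5.97 ± 0.68 and 19.4 ± 0.74 CPM to 0.32 ± 0.16, 0.10 ± 0.01 and 0.88 ± 0.30 CPM; in P0_array they stood at 11.56 ± 6.76, 8.15 ± 6.63 and 18.17 ± 6.48 CPM. They were followed by ZC317.7 (591.1 ± 87.9 to 43.2 ± 6.86), Y73F8A.26 (92.35 ± 11.2 to 9.03 ± 5.01), Y57G11C.8, C55C3.3 (36.51 ± 1.15 to 4.22 ± 0.34), the cullin cul-5, T20F7.1 and bath-19. The 3 histone genes were the called members of 53 (5 adjusted over the list alone, camera adjusted p = 0.0114, and adjusted p = 0.534 with an estimated correlation), and as near-identical copies their single levels are uncertain. The whole list took 0.782% and 0.818% of counts in F3_fertile and 0.744% to 0.779% in P0_wt. Its share of counts was thus not lower in F3_fertile. Of the 24 genes of these 42 with at least 1 CPM in P0_wt, 18 were called in the same direction in P0_array, 21 in F3_subfertile and 16 in both, and the other 18, all rises from under 1 CPM, were called in both. None of the 42 calls remained when any 1 of P0_wt replicates 1, 2 and 3 was left out. The number of calls was 26 without P0_array replicate 2 and 200 without F3_fertile replicate 3. All 3 comparisons share P0_wt, so part of the agreement may come from these controls. With no group changed, P0_array and F3_fertile against P0_wt shared a mean of 0.03 calls in 30 simulations. P0_array against P0_wt had a mean of only 0.2 calls in them. The shared number was thus bound to be near 0 and does not measure the part of the controls.

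**Figure D2:**
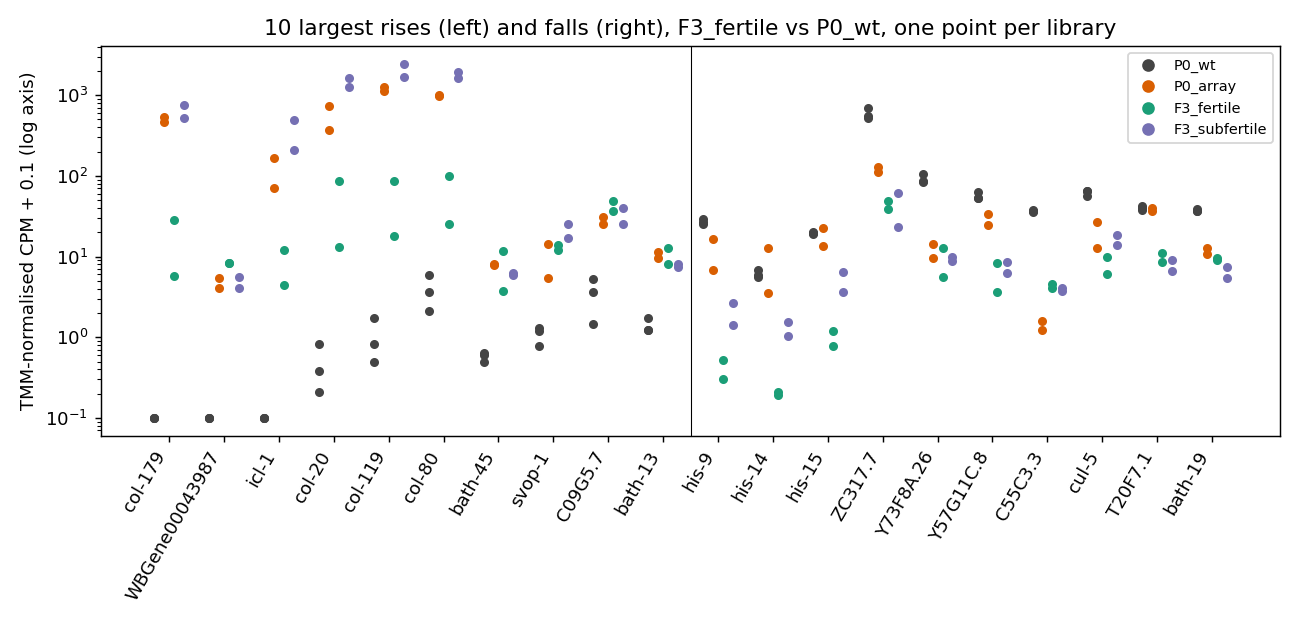
TMM-normalised CPM plus 0.1 (log axis) of the 10 largest rises and the 10 largest falls in F3_fertile against P0_wt, with 1 point per library and colours for the 4 groups. C55C3.3, for example, was near 36.51 CPM in P0_wt and at 1.31 to 4.22 CPM in the means of the other groups.

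The H3.3 and mes genes were not called in F3_fertile. Camera placed P granule genes (median log2 -0.13, adjusted p = 0.0448), apoptosis and DNA damage genes (-0.25, 0.0381), gonad and basement membrane markers (-0.47, 0.00963) and sex determination genes (-0.23, 0.0439) lower, and cytosolic ribosomal proteins (0.21, 8.67e-05) and intestine markers (0.0364) higher, without any called member. With an estimated correlation the adjusted p of these 6 lists lay from 0.534 to 0.8. Without F3_fertile replicate 3 the 4 lower lists and other histones lost their call. Without P0_wt replicate 2 or 3 P granules, apoptosis, sex determination and intestine lost it, as did other histones without P0_wt replicate 2. Cytosolic ribosomal proteins lost it without F3_fertile replicate 1 or P0_wt replicate 3. Intestine markers also lost it without either P0_array library and turned lower without F3_fertile replicate 1 (adjusted p = 0.958). The JNK pathway, mitochondrial stress, mitochondrial genome and developmental transcription factor lists had no called member in P0_array or F3_fertile against P0_wt.

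X-linked genes were compared with autosomal genes because the MES-2/3/6 complex is known to act on the X chromosome in the germ line. Over all tested genes, the median log2 fold change of 1763 X-linked genes exceeded that of 11814 autosomal genes by 1.11 in F3_subfertile against F3_fertile (camera p = 3.90e-08, and p = 0.00049 with an estimated correlation), by 0.89 in F3_subfertile against P0_wt (p = 1.05e-05, and p = 0.00136) and by 0.63 in P0_array against P0_wt (p = 0.0158, and p = 0.017). In F3_fertile against P0_wt the medians did not differ (camera p = 0.27, and p = 0.169 with an estimated correlation). The excess in P0_array fell to 0.29 and lost its call without P0_array replicate 2. The excess was larger in the F3 comparison than in the P0 one (interaction -0.40, p = 0.00423, and p = 0.00876 with an estimated correlation) and larger in F3_subfertile than in P0_array (0.32, p = 0.00403, and p = 0.00858 with an estimated correlation). Both of these calls were lost without P0_array replicate 3, at -0.41 and 0.27. The interaction was -0.65 without P0_array replicate 2 and -0.69 without F3_fertile replicate 1. Among genes with a mean of at least 5 CPM, camera with an estimated correlation called neither the interaction (p = 0.128) nor F3_subfertile against P0_array (p = 0.104). With the preset correlation it called both (p = 0.00178 and p = 0.000671).

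Many X-linked genes are near silence in the germ line, so the comparison was repeated on 148 X-linked and 4059 autosomal genes with at least 20 CPM over P0_wt and F3_fertile, a limit chosen after the data were seen. In F3_subfertile against F3_fertile, 85.1% of these X-linked genes and 27.1% of the autosomal ones had a positive log2 fold change, and the medians differed by 0.42 (p = 0.00691 with an estimated correlation). The difference was 0.08 in P0_array against P0_wt (p = 0.246), 0.23 in F3_subfertile against P0_wt (p = 0.0707) and -0.19 in F3_fertile against P0_wt (p = 0.27), all with an estimated correlation. The P0_array libraries went opposite ways, at 0.274 in replicate 2 and -0.106 in replicate 3 against -0.051 to 0.076 in P0_wt, so 0.08 describes neither. With the preset correlation P0_array also passed the threshold (p = 0.000177, less reliable as the estimated correlation is 0.132), and among genes of 100 CPM or more the difference against P0_wt was 0.3 in P0_array (p = 0.0273 with an estimated correlation) and 0.4 in F3_subfertile (p = 0.00882). Of the calls over all genes, 6.5% of tested X-linked genes rose in F3_subfertile against F3_fertile, against 3.3% elsewhere (Fisher's exact p = 9.27e-10), as did 5.6% of genes on chromosome V (p = 2.30e-07, Fisher's exact test). On chromosomes I and III 1.7% and 1.5% rose (Fisher's exact p = 4.36e-10 and p = 5.57e-11). These tests take genes as independent, and 275 of the 508 rises started from under 1 CPM in F3_fertile.

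**Figure D3:**
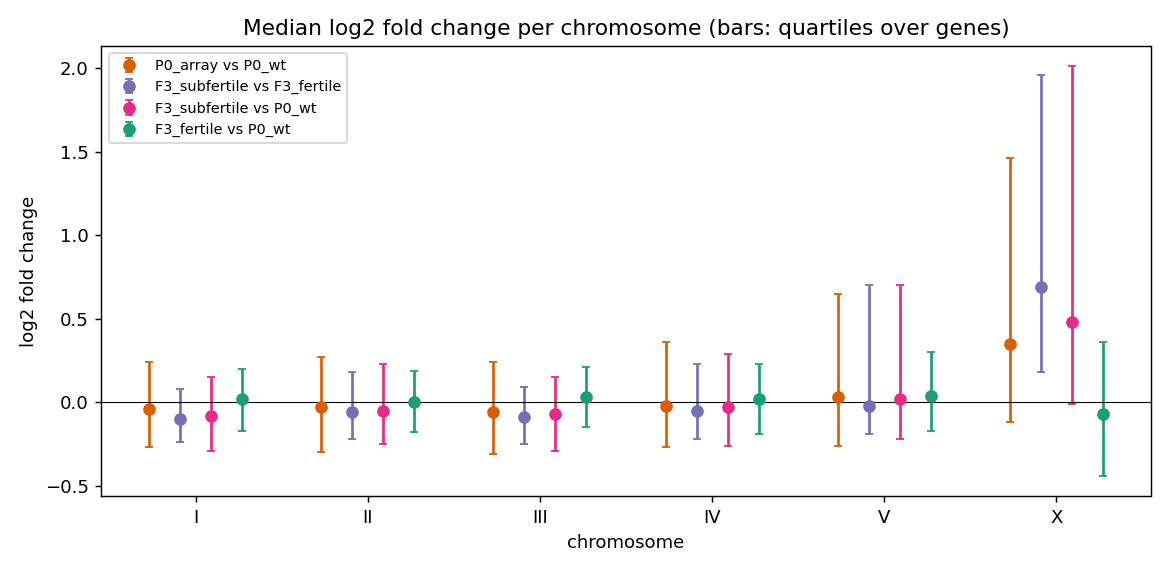
Median log2 fold change of genes with a mean of at least 5 CPM on each chromosome in 4 comparisons, with bars from the lower to the upper quartile over genes. The X-linked median was 0.69 in F3_subfertile against F3_fertile and -0.07 in F3_fertile against P0_wt, and the autosomal medians lay between -0.10 and 0.04.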

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

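The tests of technical explanations in this part were all chosen after the results were seen, and several replaced an earlier test; the interaction itself was planned.

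The effect in the P0 animals differed from the effect in the F3 animals at 3 genes by edgeR's interaction test. For dhs-25, a short-chain dehydrogenase gene on X, P0_array minus P0_wt was 0.55 ± 0.15 (SE, log2) and F3_subfertile minus F3_fertile 3.32 ± 0.18, a difference of -2.77 ± 0.23 (adjusted p = 0.0147). For C55C3.3 the effects were -4.79 ± 0.29 and -0.14 ± 0.26, a difference of -4.66 ± 0.37 (adjusted p = 0.0147), with F3_fertile already low. For acs-1 they were -0.9 ± 0.22 and 2.28 ± 0.24, a difference of -3.18 ± 0.32 (adjusted p = 0.0406). Each call was lost without P0_wt replicate 1 or 3, P0_array replicate 2 or 3 or F3_subfertile replicate 1, and those of C55C3.3 and acs-1 also without P0_wt replicate 2; none of the 3 was kept with the replicate block.

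Transcripts of intestine, cuticle and muscle genes were high in both subfertile groups. Scaling is argued against as the cause: the share of raw counts from silent genes in the lowest subfertile library was 12.2 times that in the highest fertile library, while the TMM factors differed by 1.54 times at most. Adult tissue carried over with the dissected germ lines may account for the pattern and stays open: 15 of 15 larval molting genes were under 20 CPM in both subfertile groups (highest mean 6.85 CPM), as adult tissue needs, but they are as low in P0_wt, and the list was made after larval collagens had been seen near 0. In that earlier test 3 of 3 adult collagens and 0 of 8 larval ones reached 20 CPM in both groups. Carried-over tissue and transcription of these genes in the germ line itself cannot be told apart here, because no library of soma was used and every subfertile library shows the pattern.

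X-linked genes were higher in F3_subfertile than in F3_fertile. Near-silent genes on X are argued against as the whole cause, since X-linked genes stood above autosomal ones by 0.42 also among genes of at least 20 CPM (p = 0.00691 with an estimated correlation); that limit was first set on the P0_wt mean and moved to the mean of both fertile groups after the data were seen. Carried-over tissue could raise X-linked genes in P0_array too, where the difference was 0.08 (0.274 in replicate 2 but -0.106 in replicate 3, which had the most counts from silent genes; p = 0.246 with an estimated correlation, p = 0.000177 with the preset one) and 0.3 among genes of 100 CPM or more (p = 0.0273 with an estimated correlation); the interaction on this set had p = 0.117 with an estimated correlation, so it cannot be told apart. Part of the contrast came from F3_fertile, whose X-linked genes were at -0.19 against P0_wt. A difference in the germ line between fertile and subfertile descendants was not tested apart from these.

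Of the genes with at least 1 CPM in P0_wt, 24 were called in F3_fertile against P0_wt, 9 up and 15 down. A fixed difference between the control line and the others would not by itself make F3_subfertile and P0_array differ at these genes. By over 2 SE, 14 of the 24 differed between them, against 14.4% of all tested genes. The exact binomial p was 7.86e-07, which takes genes as independent, and 11 of 21 differed without histone genes. The count was lower without P0_array replicate 3 or F3_subfertile replicate 1. This cannot decide, since the 2 groups also differ in generation and tetracycline. They may thus differ at these genes beside a line difference. In between, a version on the 16 genes called the same way in all 3 comparisons against P0_wt gave 6 of 16, but it decides nothing, since those genes were picked for being alike in both groups. The 14.4% is not a matched rate for the 24, since picking called genes favours a small SE, so the binomial p is too small. A linked region that differs in sequence may account for part and cannot be told apart: 10 pairs of the 24 lay within 1 Mb (4 without the histone genes), against a mean of 6.42 and a 95% limit of 11 in 10000 random sets, and 10 of the 24 lay on chromosome II, which holds 2388 of 13590 tested genes; earlier versions found 17 pairs among all 42 calls (random mean 19.55, 95% limit 28) and 3 among the 16 (2.77 and 6). A line difference stays open for all 24 genes beside the P0_wt libraries and descent from array animals. The labels give the controls as both N2 and FAS158. Of the 14 genes beyond 2 SE, 6 were called the same way in all 3 comparisons against P0_wt. No call remained whichever P0_wt library was left out, so these losses do not point to 1 library.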

How the results depend on the processing

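The alternatives on genes of 20 CPM or more in the fertile groups, and those run on the X chromosome and on the overlaps other than genes of at least 5 CPM, were chosen after the data were seen. Each group has 2 or 3 libraries, and a group reduced to 1 library is assumed to vary like the others. Of 185 named gene calls, DESeq2, limma-trend and the strict filter kept 185, no filter 183, RLE scaling 180, upper-quartile scaling 179, the test against 1.5-fold 149, and left-out libraries 97; fits of only the groups compared kept 159 of 182. Of 57 list calls, the estimated correlation kept 1, fry 24 and left-out libraries 39. None of these gene calls reversed; among lists, intestine markers in F3_fertile against P0_wt turned lower than other genes without F3_fertile replicate 1 (mean log2 0.084, and 2.807 without replicate 3). The causes were not tested.

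Genes changed in P0_array against P0_wt, F3_subfertile against F3_fertile, F3_subfertile against P0_wt, F3_fertile against P0_wt, F3_subfertile against P0_array and the interaction numbered 2535, 1520, 2271, 418, 351 and 289 with DESeq2 and 2480, 1548, 2161, 78, 261 and 6 with limma-trend. In simulated data DESeq2 made 113 false calls and limma 6. The simulated means were pooled over all libraries, unlike the many rises from 0 counts here, so the simulation does not settle which number is nearest. Among genes of 20 CPM or more in the fertile groups they numbered 157, 60, 128, 26 and 10 in the first 5, where fewer genes were tested. Without a filter they numbered 844 in F3_subfertile against F3_fertile, 117 in F3_fertile against P0_wt, 50 in F3_subfertile against P0_array and 33 in the interaction. The test against 1.5-fold left 25 in F3_fertile against P0_wt; for F3_subfertile against P0_array the strict filter gave 2 and the fit of only these groups 0, where edgeR gave 1, with 1263 genes at an unadjusted p under 0.05.

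Leaving out each library in turn gave from 573 to 1624 genes in P0_array against P0_wt, 167 to 590 in F3_subfertile against F3_fertile, 566 to 1498 in F3_subfertile against P0_wt, 0 to 200 in F3_fertile against P0_wt, 1 to 34 in F3_subfertile against P0_array and 0 to 41 in the interaction. The X-linked difference ran from 0.29 to 0.67 in P0_array against P0_wt, from 0.2 to 0.49 in F3_subfertile against P0_array and from -0.69 to -0.29 in the interaction. In F3_fertile against P0_wt it was -0.19 among genes of 20 CPM or more, past the threshold with the preset correlation only. Shared calls of the comparisons with P0_wt ran from 490 to 1150 and r from 0.58 to 0.81; those without a shared library ran from 148 to 510 and r from 0.37 to 0.57. The former were 560 with r = 0.94 (rho = 0.685) at 5 CPM or more, 1629 with DESeq2, and 73 with r = 0.88 (rho = 0.565) at 20 CPM or more; the latter had r = 0.85 (Spearman rho = 0.373) at 5 CPM or more, 1020 calls with DESeq2, and 35 with r = 0.68 at 20 CPM or more, where rho = 0.091 shows almost no agreement in rank.

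Whether equal replicate numbers mark a shared day is not known: over 10 same-number pairs the correlation of deviations ran from -0.07 to 0.27, with a median of 0.09, and the pairs above 0.1 all included F3_fertile. With the replicate block, which leaves 3 residual degrees of freedom, 712, 715, 2, 0 and 1 genes were called in P0_array, F3_subfertile and F3_fertile against P0_wt, F3_subfertile against P0_array and the interaction (a rise, none of the 3 falls), the shared calls were 553, and 120 of 185 gene calls and 52 of 57 list calls were kept.

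Upper-quartile scaling lowered log2 fold changes by 0.22 in P0_array against P0_wt, 0.19 in F3_subfertile against F3_fertile and 0.23 in F3_subfertile against P0_wt. It turned the medians below 0 of gonad markers and mitochondrial genome genes in the first, of sperm, H3.3 and mitochondrial stress genes in the next, and of sperm, both histone, cytosolic ribosomal and stress lists in the last.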

Other observations

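The values in this part were looked at after the data were seen. The most abundant transcript was that of the vitellogenin gene vit-5 in both F3_subfertile libraries, at 6.71% and 4.32% of counts, and that of the elongation factor gene eef-2 in the other 7 libraries, at 3.65% to 6.12%. The tissue markers did not keep 1 ratio across the subfertile libraries. Vitellogenin counts were 6.42 and 1.52 times collagen counts in P0_array and 10.6 and 6.93 times in F3_subfertile, while muscle marker counts were 0.22, 0.215, 0.192 and 0.226 times collagen counts.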
